A study of Homo sapiens with 6 samples.

How the data were processed

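RNA was sequenced from HGC-27 cells 72 h after transfection with an siRNA pool against STRN3 or a negative control siRNA, with 3 libraries per treatment, per the labels' protocols. Groups and replicate numbers come from the sample titles. The labels name extraction with TRIzol and Illumina library preparation, and no step that enriches polyadenylated RNA or removes ribosomal RNA is named in the sources used here.

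The authors deposited a table with 58233 gene rows, 2 rows without a gene, and values in TPM per library, per the file headers, although its name gives FPKM. The TPM values sum to 985805 to 987429 in the siNC libraries and to 966433 to 968756 in those labelled siSTRN3, so 12571 to 14195 and 31244 to 33567 TPM belong to rows not analysed here. The submitters' processing notes list HISAT2, Cufflinks and RSEM without versions or roles, and the build GRCh38.p10; the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The table also holds the authors' p-values and adjusted p-values, for which the file name gives DESeq2, and a yes or no call; these are quoted only as the authors' deposited table. TPM scales every library to one total, so a class of RNA that takes more of the total lowers all other values, and it keeps no read depth, so depth is unknown and no counting interval can be given. Rows nearly match genes (56569 symbols, 215 of them on several rows), so no rows were summed; transcript types and coordinates come from GENCODE release 29 (GRCh38) by unique symbol, for 12726 of the 13004 tested rows.

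The analysis foreseen before the data were examined was limma-trend on log2(value + 1) of FPKM; because the values are TPM, the same test was run on log2(TPM + 1). Rows with at least 1 TPM in at least 3 libraries were tested, 13004 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05 (limma 3.58.1, R 4.3.3, and the package data.table, version 1.17.8). The design had no block. Each result was computed on the deposited scale and after every library was multiplied by 1 factor that gave all libraries the same median over the tested rows; the latter, an alternative chosen before the data were examined, is called relative to the median gene. Because the median moved by more than 0.1, changes of single genes and lists are given on that scale. STRN3 was also tested with an exact 2-sided permutation test, whose smallest p for 3 against 3 is 0.1. RNA classes were summed from the TPM of rows by type and symbol; the ribosomal class holds the named rows and 6 unnamed clone rows within 30 kb of a 5.8S gene.

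Before the data were examined, 26 gene lists were fixed: STRIPAK, Hippo, YAP/TAZ targets, G1/S, G2/M, p53, apoptosis, epithelial-mesenchymal and matrix, epithelial junction, actin and SRF, interferon, NF-kB, AP-1, ATF4 and unfolded protein response, cholesterol, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded, histones, gastric lineage, Wnt, TGF-beta, and leukocyte, endothelial and fibroblast markers. Those with 5 or more measured genes (22) were tested with camera at a preset correlation of 0.01, adjusted over these lists, with camera at an estimated correlation and fry beside it. On log2(TPM + 1) a common factor moves high rows more than low ones, so camera on the deposited scale also responds to the level of a list's genes. The genes named are STRN3; the 10 highest and 10 lowest fold changes among protein-coding or otherwise named genes with adjusted p under 0.05, a mean of at least 5 TPM and groups that do not overlap; and from each list up to 4 members with the smallest adjusted p, or the 2 with the highest level where none passed. The rule was applied on both scales; where the text gives another gene, it says so or names it as a reference gene of its list.

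Near-identical copies of the genes that could be named were searched with blastn (BLAST+ 2.17.0), taking the longest transcript against all GENCODE release 29 transcripts at 95% identity or more over at least 50% of its length. Exon overlaps with genes at a mean of 1 TPM or more were taken on either strand, since the strand setting is not known. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

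The fit was tested on simulated data: 13004 genes drawn with the measured means and spreads, 200 of them changed, with the same common shift. Relative to the median gene, 45 of 100 genes changed 1.5-fold and 78 of 100 changed 2-fold were recovered, and 7 of 12804 unchanged genes were called; on the deposited scale 11223 of these unchanged genes were called. All 20 simulated lists of 20 genes moved 1.5-fold were called by camera and 0 of 20 unmoved lists. The simulated genes varied independently, so this cannot show how often camera calls unmoved lists whose genes vary together. Of the lists called relative to the median gene, only histones had a median fold above 1.5 (1.97). Cholesterol biosynthesis came next at 1.34, so recovery of smaller shifts was not simulated. The alternatives tried were rescaling, no filter, a filter of 5 TPM, the replicate number as a block, leaving out each library, a pseudocount of 0.1, limma without the trend, a 2-fold threshold, and the other list tests; TPM over protein-coding rows, summed rows and removal of a smooth trend on length and GC content (known for 97.8% of the tested rows) were added after the data were seen. The other foreseen alternatives were not run because they need a table per transcript or read counts.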

Results

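The transcriptome of HGC-27, a cell line from an undifferentiated human gastric cancer, was measured by RNA sequencing 72 h after transfection with a pool of siRNAs against STRN3 or with a negative control siRNA. STRN3 encodes striatin-3, a regulatory subunit of protein phosphatase 2A within the STRIPAK complex, which acts on the kinases of the Hippo pathway. Each treatment had 3 libraries, called siNC and siSTRN3 after their labels. The deposited table gives 58233 gene rows in TPM, a length-corrected share of each library's total, with 13264 to 13327 rows at 1 TPM or more in the siNC libraries and 12295 to 12324 in those labelled siSTRN3. TPM keeps no read number, so the depth behind each value is unknown. The labels do not say whether the 3 libraries of a treatment came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Across genes, log2(TPM + 1) correlated at 0.981 to 0.989 between libraries of one group and at 0.973 to 0.976 between groups.

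The first question was whether the targeted gene was lower. STRN3 (chromosome 14, 30893799 to 31026401, GRCh38) was not lower in the libraries labelled siSTRN3. Its level was 3.51, 5.30 and 3.85 TPM in the siNC libraries (mean 4.22 ± 0.951 SD, n = 3) and 4.76, 5.0 and 5.56 TPM in the libraries labelled siSTRN3 (mean 5.11 ± 0.411 SD, n = 3). As deposited, the log2 fold change was 0.24 ± 0.14 SE (limma, adjusted p = 0.142; exact 2-sided permutation test p = 0.3). Relative to the median gene STRN3 rose by 0.78 ± 0.13 SE (adjusted p = 0.00896), with all 3 libraries labelled siSTRN3 above all 3 siNC libraries and an exact permutation p of 0.1, the smallest that 3 against 3 can give. The deposited-scale difference passed the threshold only without siNC replicate 2 (log2 fold change 0.38, adjusted p = 0.0137). No other annotated gene in the table had a transcript nearly identical to that of STRN3, and no other expressed gene overlapped its exons. The measured STRN3 level goes against the label, so the groups are named by label throughout and every direction given here is that of the libraries labelled siSTRN3 over those labelled siNC.

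**Figure D1:**
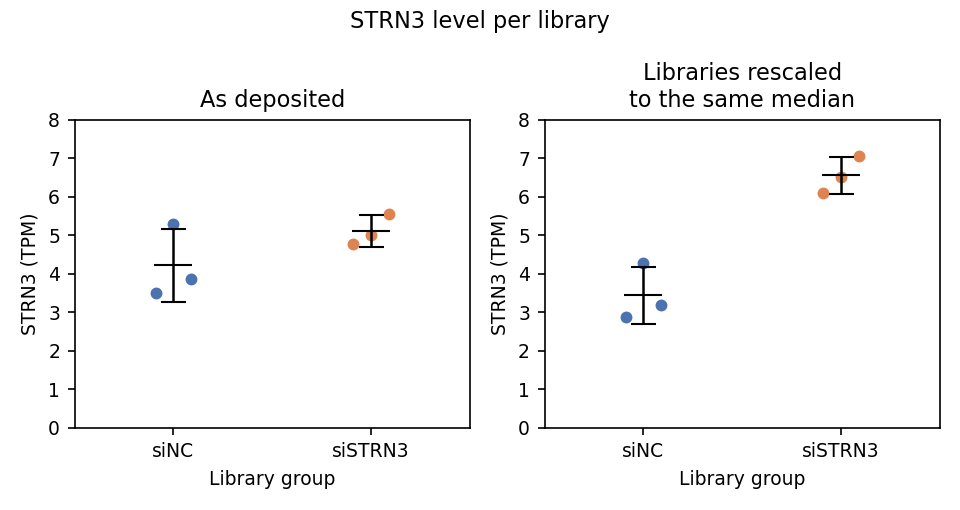
STRN3 level in TPM per library (points) with the group mean and SD (bars, n = 3), as deposited and after the libraries were rescaled to the same median. The siNC libraries held 3.51 to 5.30 TPM and the libraries labelled siSTRN3 4.76 to 5.56 TPM as deposited.

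The makeup of the RNA differed between the groups, with more ribosomal and other structural RNA in the libraries labelled siSTRN3. Rows of the nuclear ribosomal RNA repeat went from 17% ± 0.728 to 43% ± 0.666 (SD, n = 3) of the TPM total. Other structural RNAs that are not polyadenylated took larger shares too. Together 7SK, RMRP and RPPH1 went from 0.104% ± 0.0179 to 0.262% ± 0.00689. The RNA of the signal recognition particle, 7SL, went from 0.416% ± 0.0466 to 0.662% ± 0.0184, and small nuclear, nucleolar and Cajal body RNAs from 0.107% ± 0.00756 to 0.267% ± 0.0302. Mitochondrial ribosomal RNA went from 0.500% ± 0.00659 to 0.768% ± 0.0122. The share of mitochondrial messenger RNA was lower, from 9.17% ± 0.293 to 6.39% ± 0.183, as was that of protein-coding genes other than histones, from 68.4% ± 0.427 to 45.8% ± 0.487. In each of these classes the groups did not overlap, and the exact 2-sided permutation p was 0.1, the smallest possible.

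**Figure D2:**
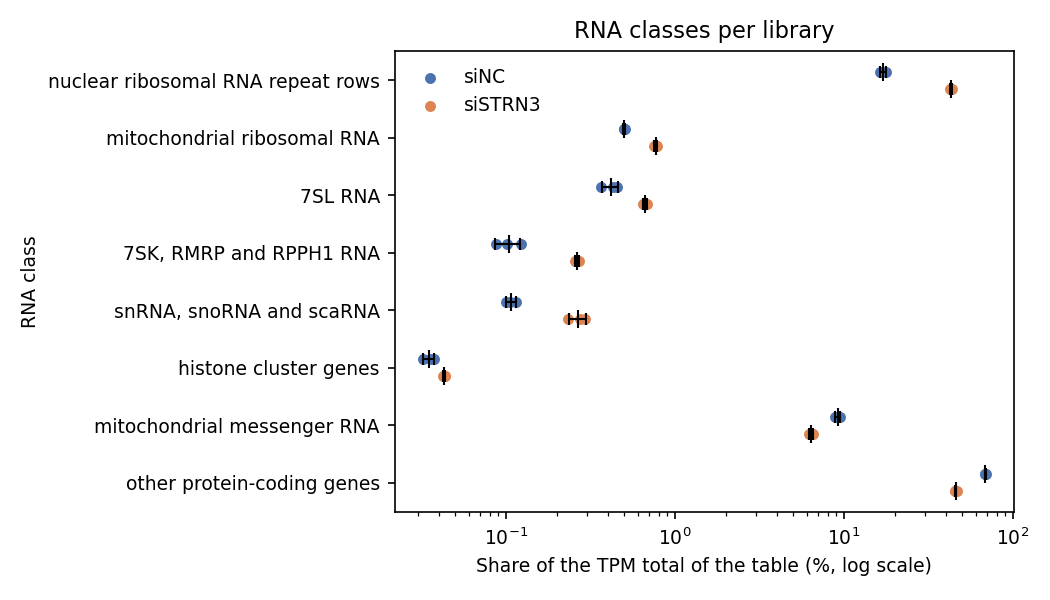
Share of the summed TPM of the table held by each RNA class (log axis, percent), per library (points), with the group mean and SD (bars, n = 3). Ribosomal RNA rows held 17% of the total in the siNC libraries and 43% in those labelled siSTRN3.

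TPM is a share of one total, and most other genes were lower in the libraries labelled siSTRN3. On the deposited scale 10643 of 13004 tested rows changed (limma-trend on log2(TPM + 1), adjusted p under 0.05), 131 higher and 10512 lower, and the median log2 fold change was -0.57. After the libraries were rescaled to the same median, 2772 rows changed, 1424 higher and 1348 lower, of which 91 were higher and 24 lower by 2-fold or more. At an unadjusted p under 0.05, 4774 rows passed. With TPM recomputed over protein-coding rows alone, the split was 1084 higher and 1986 lower. Those values were not rescaled to the median gene, and their median log2 fold change was -0.051, against -0.0062 after rescaling. The groups did not overlap in 5519 rows after rescaling (42.4%, against 10% by chance). Of the 1424 rows higher relative to the median gene, 1073 lay below 0 on the deposited scale, and of the 1348 lower ones none lay above 0. From here on, fold changes are relative to the median gene on the log2(TPM + 1) scale, which understates changes of low genes, and rose and fell are used in that sense. Levels in TPM are given as deposited, before rescaling, so their ratio differs from the fold change beside them. The rescaled count was 1508 to 1604 when any one siNC library was left out, more than 1.5 times lower.

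**Figure D3:**
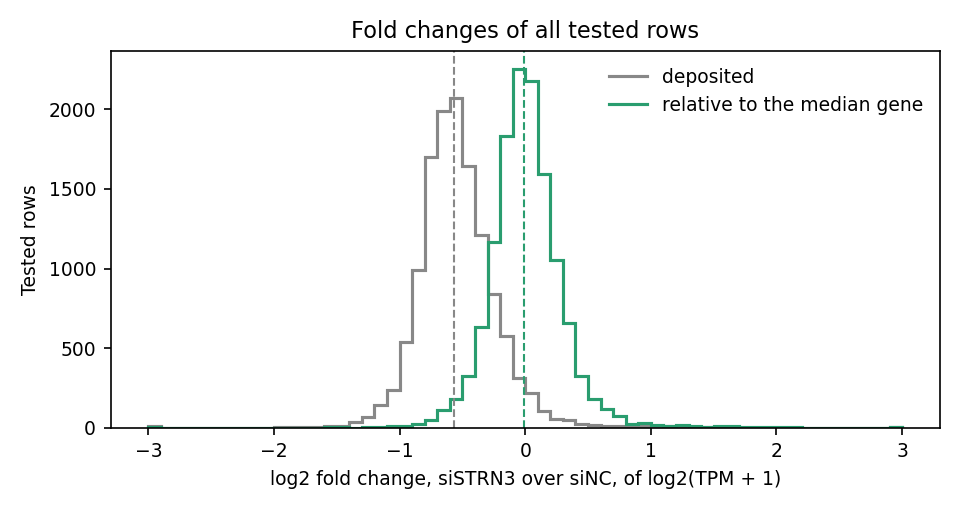
Number of tested rows per 0.1 of log2 fold change, siSTRN3 over siNC, on the deposited scale and relative to the median gene; dashed lines mark the medians, and values beyond 3 are counted in the end bins. The deposited distribution is centred at -0.57.

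Most of the largest changes were in structural RNA genes or in rows with near-identical copies. HFM1, LEAP2 and CLIC5 were among the exceptions. RN7SK, the 7SK RNA that holds the elongation factor P-TEFb, rose from 665 ± 94.5 to 1740 ± 29.6 TPM (log2 fold change 2.05 ± 0.10 SE, adjusted p = 1.25e-04; 2.04 when summed with its copies). The RNA of RNase MRP, RMRP, rose on the higher of its 2 rows from 154 ± 30.1 to 399 ± 31.1 TPM (log2 fold change 2.03 ± 0.14 SE, adjusted p = 4.98e-04). The 3 rows named RNA5-8S5, the 5.8S ribosomal RNA, rose by 1.88 to 2.18. RN7SL4P (2.01), RNVU1-18 (2.28), SNORA73A (3.82) and a U1 row (5.01) were also among the 10 highest, but each shares sequence with other genes, so its value is uncertain. Summed with SNHG3, the gene that overlaps it and its only match, SNORA73A stood at 1.06. With their copies RN7SL4P stood at 1.30 and RNVU1-18 at 1.97, the latter without the rows named U1. The call of SNORA73A ended without any one library except siNC replicate 2 and siSTRN3 replicate 3 (adjusted p = 0.0692 to 0.112), and that of the U1 row without any except siNC replicate 1 (0.0711 to 0.116). Another U1 row was listed at 0 in all 3 libraries labelled siSTRN3 and was the lowest row named by the rule. In the siNC libraries that row held 162.35, 126.41 and 196.76 TPM, against 162.39, 126.41 and 196.76 TPM for RNVU1-18. All 148 rows named for the U1 small nuclear RNA summed to 1192 ± 21.4 TPM in the siNC libraries and 2465 ± 145 TPM in those labelled siSTRN3, a relative log2 fold change of 1.70. HFM1, a DNA helicase gene of meiosis, rose (log2 fold change 2.11 ± 0.36 SE, adjusted p = 0.00944), with values that ranged widely within the groups (688 ± 203 to 1944 ± 773 TPM).

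Of the 10 lowest rows, USP41, PSMC1P1, SMIM11B and DHFRP1 have near-identical copies among expressed genes. DLEU1_1 and FAM103A2P were not found by name among the annotated transcripts, so their copies were not searched. GTF2IP13 is annotated as a pseudogene, although the search found no near-identical copy or exon overlap for it. All 7 are taken as uncertain. FAM103A2P kept its call in the leave-outs only without siSTRN3 replicate 1 (otherwise adjusted p = 0.0777 to 0.099 with 1 library left out). Summed with its copies, PSMC1P1 stood at -0.12 against -3.38 alone, DHFRP1 at -0.33 against -2.92, SMIM11B at 0.059 against -3.04, and USP41 at -1.92 against -4.73. LEAP2, an antimicrobial peptide gene, fell from 17 ± 2.45 to 0.897 ± 0.343 TPM (log2 fold change -2.80 ± 0.16 SE, adjusted p = 2.33e-04) and CLIC5, an intracellular chloride channel gene, from 11.7 ± 3.28 to 0.623 ± 1.08 TPM (log2 fold change -2.79 ± 0.49 SE, adjusted p = 0.0105).

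Among protein-coding genes with no near-identical copy or exon overlap, a restriction added after the values were seen, IGFBP3, which encodes an insulin-like growth factor binding protein, fell from 65.6 ± 2.95 to 12.7 ± 0.927 TPM, 3.16-fold relative to the median gene (log2 fold change -1.66 ± 0.059 SE, adjusted p = 3.34e-05). SFRP4, a secreted Wnt antagonist, fell 2.83-fold (log2 fold change -1.50 ± 0.057 SE, adjusted p = 4.19e-05) and GPNMB, a transmembrane glycoprotein, 2.42-fold (log2 fold change -1.27 ± 0.046 SE, adjusted p = 3.34e-05). KDM6B (-1.09), SPACA9 (-0.97), SLC41A3 (-0.85) and the small heat shock protein gene CRYAB (-0.83) fell as well, and AMH fell (-0.91; adjusted p = 0.0557 without siNC replicate 3). On the rising side the 10 highest genes under the same restriction were HFM1, 8 histone genes and ACTG1, the gene of cytoplasmic gamma-actin. ACTG1 rose from 585 ± 47.7 to 833 ± 34.5 TPM (log2 fold change 1.16 ± 0.069 SE, adjusted p = 2.33e-04). The copy search covered annotated transcripts only, so reads from unannotated repeated sequence could still count toward HFM1.

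The gene lists fixed beforehand were tested on both scales. Relative to the median gene camera called 10 of 22 lists, 7 up and 3 down, and 1 of them with an estimated correlation. With the deposited values it called 8, cholesterol biosynthesis and histones higher than other genes, and G2/M, epithelial-mesenchymal and matrix, actin, ATF4, oxidative phosphorylation and ribosomal protein genes lower. The call for histones, 1 of these, held with an estimated correlation. Relative to the median gene, estimated correlations were under the preset 0.01 for the Wnt (-0.043), G1/S (-0.017) and epithelial-mesenchymal lists (0.0042). Those of the hypoxia and glycolysis (0.0042) and oxidative phosphorylation lists (0.0043) were too. The loss of these calls therefore does not come from a correlation above the preset one. The TGF-beta (0.075), histone (0.050), ribosomal protein (0.20) and mitochondrially encoded lists (0.56) had higher ones.

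Genes of cholesterol biosynthesis rose together. Of 24 measured genes 19 rose and 1 fell (19 rose and 1 fell when adjusted over the list alone), and the list median was 0.42, while on the deposited scale 3 were higher and 13 lower, with a median of -0.22. HMGCS1, which makes HMG-CoA for the mevalonate pathway, rose from 38.4 ± 1.17 to 49.2 ± 2.53 TPM (log2 fold change 0.98 ± 0.043 SE, adjusted p = 7.21e-05). MSMO1 (0.74, adjusted p = 3.55e-04), FDFT1, the squalene synthase gene (0.63, adjusted p = 3.44e-04), and SQLE, the squalene epoxidase gene (0.50, adjusted p = 3.09e-04), rose. So did INSIG1, the sterol-regulated anchor of SREBP processing (1.06, adjusted p = 9.53e-04), named after its value was seen. PMVK fell (-0.18, adjusted p = 0.0482). The list was called against all other genes (camera, adjusted p = 2.68e-11), and relative to the median gene it was the only one of the 22 lists tested whose call held with an estimated correlation (adjusted p = 0.0308).

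Replication-dependent histone genes had the highest median of the lists tested, 0.98, and were also above 0 on the deposited scale, at 0.50. Of 20 measured genes 14 rose and 1 fell (17 rose and 1 fell when adjusted over the list alone; camera, adjusted p = 3.41e-09; adjusted p = 0.0853 with an estimated correlation). HIST1H1B rose from 5.37 ± 1.09 to 14.3 ± 0.560 TPM (1.85, adjusted p = 3.68e-04), HIST1H1E from 6.82 ± 0.949 to 16.9 ± 0.915 TPM (1.80, adjusted p = 1.82e-04), HIST1H3B by 1.58 and HIST1H1D by 1.44, while HIST1H2BK fell (-0.24, adjusted p = 0.0428). Most of these messenger RNAs end in a stem-loop in place of a poly(A) tail, although HIST1H2BK is among those also known in a polyadenylated form. The shares of ribosomal and other structural RNA were higher in the same libraries. Genes of G1/S and DNA replication moved less: of 36, 13 rose and 2 fell (15 rose and 2 fell when adjusted over the list alone), with a median of 0.13 (camera, adjusted p = 0.00321; adjusted p = 0.0853 with an estimated correlation) against -0.51 on the deposited scale. SLBP, which binds the histone stem-loop (0.36, adjusted p = 0.00373), GINS2 (0.35) and FEN1 (0.19) rose and MCM7 fell (-0.20). Genes of G2/M and mitosis went both ways, 8 up and 8 down of 34 (11 rose and 11 fell when adjusted over the list alone; camera, adjusted p = 0.983): PLK1, the mitotic kinase gene, fell (-0.54, adjusted p = 6.11e-04) and KIF2C fell (-0.29), whereas TOP2A (0.49) and ANLN (0.54) rose. The median was -0.010, the mean 0.040, and camera's direction was down.

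The lists closest to the design were those of the STRIPAK complex, the Hippo pathway and the targets of its effectors YAP and TAZ. Of 20 STRIPAK genes 3 rose and 4 fell (4 rose and 4 fell when adjusted over the list alone; camera, adjusted p = 0.983). Besides STRN3, STK26, a kinase of the complex, rose (0.27, adjusted p = 0.0133; adjusted p = 0.0539 without siNC replicate 1), and PPP2R1A, the scaffold subunit of protein phosphatase 2A, fell (-0.52, adjusted p = 0.00251), as did MINK1 (-0.38, adjusted p = 0.00906) and STRN4 (-0.20, adjusted p = 0.0223). The other called genes were PPP2CA, outside the naming rule, which rose (0.15, adjusted p = 0.0202), and PPP2CB, which fell (-0.14, adjusted p = 0.0390). Of 28 Hippo pathway genes 1 rose and 3 fell, also when adjusted over the list alone (camera, adjusted p = 0.983). VGLL4, a TEAD cofactor that competes with YAP, fell (-0.56, adjusted p = 0.00186), WWTR1, which encodes TAZ, fell (-0.43, adjusted p = 0.00573), AMOTL2 fell (-0.45) and NF2 rose (0.29). The call of NF2 ended without any one library except siSTRN3 replicate 1 (adjusted p = 0.0721 to 0.106) and that of AMOTL2 without siNC replicate 1 or 2 (0.059 and 0.0516). For both lists the median and the mean lay above 0 while camera's direction was down. None of 17 YAP and TAZ target genes rose and 4 fell, IGFBP3, AXL (-0.36, adjusted p = 0.0114), AMOTL2 and CCDC80 (-0.57; adjusted p = 0.0637 to 0.095 without siNC replicate 1 or 2 or siSTRN3 replicate 1 or 3). In this list 1 rose and 4 fell when adjusted over the list alone. CYR61, a frequently used target named later, stood at -0.093, adjusted p = 0.429. The list was not called against other genes (camera, adjusted p = 0.490), while its members moved down on balance by fry (adjusted p = 0.00263). With deposited values none of the genes of the 3 lists was higher and 17, 25 and 13 were lower.

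Camera called the Wnt, TGF-beta and epithelial-mesenchymal lists lower than other genes, and none of these calls held with an estimated correlation. Of 14 Wnt targets 8 fell and 1 rose (1 rose and 10 fell when adjusted over the list alone), with a median of -0.27 (camera, adjusted p = 0.00142; adjusted p = 0.0853 with an estimated correlation). AXIN2, the negative-feedback target of the pathway, fell from 39.2 ± 2.13 to 18.3 ± 1.22 TPM as deposited (-0.43, adjusted p = 0.00432). MYC fell from 232 ± 4.64 to 125 ± 0.392 TPM as deposited, and from 189 to 161 TPM after rescaling (-0.24, adjusted p = 0.00219). APCDD1 (-0.38) and DKK1 (-0.60), both Wnt antagonists, fell. Of 13 TGF-beta and SMAD targets 4 fell and none rose (0 rose and 4 fell when adjusted over the list alone; median -0.16; camera, adjusted p = 0.00432; adjusted p = 0.204 with an estimated correlation). They were ID1 (-0.22), ID2 (-0.46), ID3 (-0.49, adjusted p = 8.19e-04) and BAMBI (-0.49), which are known targets of bone morphogenetic protein signalling. BAMBI lost its call without any one siNC library (adjusted p = 0.0547 to 0.0747) and ID2 without siNC replicate 3 (0.051). Of 27 epithelial-mesenchymal and matrix genes 8 fell and 2 rose (3 rose and 10 fell when adjusted over the list alone; median -0.11; camera, adjusted p = 0.0418; adjusted p = 0.204 with an estimated correlation). That list call also ended without siSTRN3 replicate 1 or 2 (adjusted p = 0.0815 and 0.0683). ACTA2, smooth muscle actin, fell from 177 ± 7.46 to 62.4 ± 1.80 TPM (-0.84, adjusted p = 1.89e-04), and the transcription factor genes SNAI2 (-0.50, adjusted p = 0.00167) and TWIST1 (-0.36, adjusted p = 0.00139) fell with COL3A1 (-0.35). As deposited, where the median of all tested rows was -0.57, the list medians were -0.86, -0.70 and -0.67, and camera did not call the Wnt (adjusted p = 0.10) or TGF-beta list (adjusted p = 0.180).

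Actin cytoskeleton genes and fibroblast markers split. Of 27 actin and SRF genes 5 rose and 9 fell (5 rose and 11 fell when adjusted over the list alone; camera, adjusted p = 0.318; fry, down, adjusted p = 0.00771). TPM4, a tropomyosin gene, fell from 427 ± 8.06 to 116 ± 0.803 TPM (log2 fold change -1.23 ± 0.027 SE, adjusted p = 4.70e-06), by the same size when summed with a near-identical row (-1.23), and CNN2 fell (-0.35), whereas ACTG1 and the cofilin gene CFL1 (0.25) rose. Of 10 fibroblast markers 3 rose and 4 fell (camera, adjusted p = 0.719; fry, down, adjusted p = 0.0456; 3 rose and 4 fell when adjusted over the list alone): COL1A1 rose (0.44, adjusted p = 0.00189) and DCN fell (-0.46, adjusted p = 0.00189), and THY1 rose (0.35; adjusted p = 0.0565 without siNC replicate 2). Of 12 listed fibroblast markers, these 10 reached the filter in this cancer line. With deposited values 1 and 0 genes of these 2 lists were higher and 26 and 9 lower.

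In the lists of energy metabolism and translation some genes rose, and most did not pass the test. Of 29 hypoxia and glycolysis genes 9 rose and 1 fell (13 rose and 2 fell when adjusted over the list alone; median 0.11; camera, adjusted p = 0.00142; adjusted p = 0.0853 with an estimated correlation). CA9, a carbonic anhydrase gene induced by HIF-1 (1.05, adjusted p = 0.00340), ALDOC (0.82, adjusted p = 0.00251), PGK1 (0.49, adjusted p = 4.90e-04) and TPI1 (0.35) rose. Of 33 nuclear-encoded oxidative phosphorylation genes 9 rose and 2 fell (11 rose and 2 fell when adjusted over the list alone; median 0.080; camera, adjusted p = 0.00285; adjusted p = 0.0853 with an estimated correlation), with UQCRH (0.24, adjusted p = 0.00454) and COX5B (0.18, adjusted p = 0.0112) among those that rose. Of 60 ribosomal protein genes 23 rose and 3 fell (30 rose and 5 fell when adjusted over the list alone; median 0.077; camera, adjusted p = 5.11e-06; adjusted p = 0.378 with an estimated correlation), RPLP1 by 0.43 and RPL3 by 0.21. Of 15 mitochondrially encoded genes 7 rose and none fell (camera, adjusted p = 0.00112; adjusted p = 0.508 with an estimated correlation; 8 rose and 1 fell when adjusted over the list alone). The ribosomal RNAs MT-RNR1 (1.58, adjusted p = 6.49e-06) and MT-RNR2 (1.05, adjusted p = 4.70e-06) led the list, with MT-ND3 at 0.23 and MT-CO2 at 0.22. With TPM recomputed over protein-coding rows, which leaves both ribosomal RNAs out, that call ended (adjusted p = 0.213). As deposited, the 4 list medians lay below 0 with the common shift of -0.57, at -0.51, -0.56, -0.57 and -0.54.

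Stress and signalling lists were not called against other genes by camera. By fry, which asks whether a list's genes move one way on balance, the p53 (adjusted p = 0.00227) and interferon lists (adjusted p = 0.0188) moved up. Of 25 p53 targets 4 rose and 2 fell (4 rose and 2 fell when adjusted over the list alone; camera, adjusted p = 0.490): CDKN1A, the cell cycle inhibitor p21, rose from 3.66 ± 0.418 to 6.22 ± 0.265 TPM (log2 fold change 1.18 ± 0.086 SE, adjusted p = 5.43e-04) and TNFRSF10B rose (0.40), whereas PLK2 (-0.68) and SESN2 (-0.47) fell. Of 30 ATF4 and unfolded protein response genes 10 rose and 9 fell (10 rose and 10 fell when adjusted over the list alone; camera, adjusted p = 0.753), the chaperones HSPA5 (0.29) and HSP90B1 (0.50) and the serine synthesis gene PSAT1 (0.49) upward and the amino acid transporter gene SLC3A2 downward (-0.61, adjusted p = 2.61e-04). Its median was above 0 and its mean below. Of 16 AP-1 and immediate early genes 2 rose and 3 fell (2 rose and 4 fell when adjusted over the list alone; camera, adjusted p = 0.983), FOS rising (1.0, adjusted p = 0.00255) and JUN (-0.69, adjusted p = 0.00299), MYC and IER2 (-0.31; adjusted p = 0.051 without siNC replicate 2) falling. Median and mean were above 0 and camera's direction down. Of 24 apoptosis regulators 3 rose and 1 fell (3 rose and 1 fell when adjusted over the list alone; camera, adjusted p = 0.256), with BID (0.38), BAD (0.34) and MCL1 (0.17) up. MCL1 kept no call without any one siNC library or siSTRN3 replicate 2 (adjusted p = 0.0508 to 0.0633). Of 14 interferon genes 2 rose and 1 fell (3 rose and 1 fell when adjusted over the list alone; camera, adjusted p = 0.356), BST2 at 0.46, ISG15 at 0.34 and STAT2 at -0.35. The call of BST2 ended without siNC replicate 1 (adjusted p = 0.051), that of ISG15 without any one library except siNC replicate 3 (0.0526 to 0.0872), and that of STAT2 without any except siSTRN3 replicate 2 (0.0661 to 0.117). Of 7 NF-kB genes CCL2 fell (-0.45, adjusted p = 0.00805) and SOD2 rose (0.34, adjusted p = 0.0107; camera, adjusted p = 0.998). With deposited values at most 1 gene of each of these lists was higher.

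Most epithelial, gastric, leukocyte and endothelial markers were under the filter. Of 22 epithelial junction and keratin genes 4 were measured and DSP, desmoplakin, rose (0.58, adjusted p = 0.00594). Of 24 gastric and intestinal lineage genes 3 were measured, among them GATA4 (0.039, adjusted p = 0.809) and CDX2 (0.21, adjusted p = 0.264). Of 18 leukocyte markers 1 was measured and did not pass the test. A single endothelial marker of 12, ESAM (-0.22, adjusted p = 0.341), was measured. These 4 lists had under 5 measured genes and were not tested as groups.

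**Figure D4:**
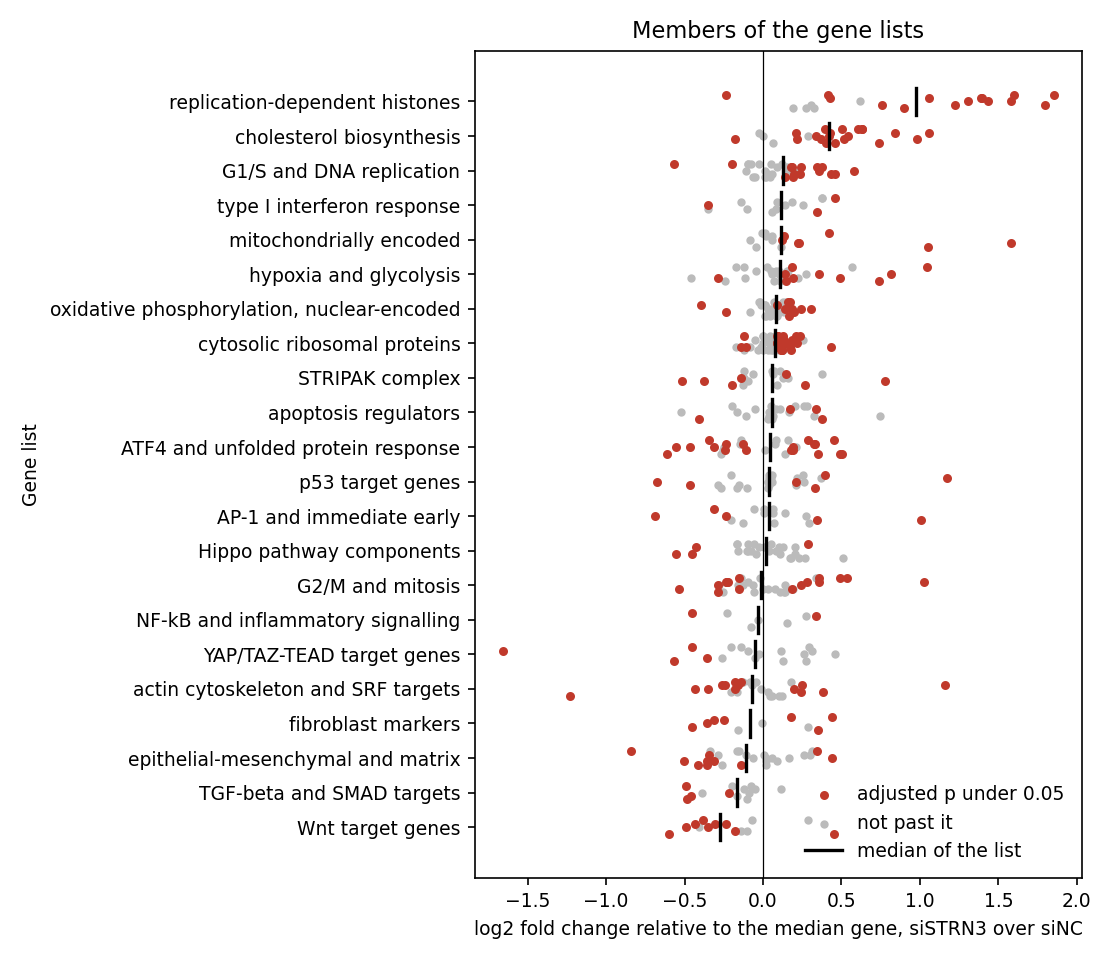
Log2 fold change relative to the median gene of each measured member of the 22 lists tested, siSTRN3 over siNC (points; red, adjusted p under 0.05; grey, not), with the list median (bar). Histones have the highest median, 0.98, and Wnt targets the lowest, -0.27.

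The naming rule applied to the deposited values also names 56 list members that it does not name on the relative scale, 56 of them lower, with log2 fold changes from -0.90 to -0.42 before rescaling. They included ACTB, AEN, ALDOA, ATP5A1, ATP5B, ATP5O, BAX, BIRC5, CALR, CCNB1, CCND1, CDC20, CLDN7, COL1A2, COX5A, ENO1, FADD, GADD45A, GAPDH, GATA6, HIST1H2BK, IFI35, JUNB, LSS, LUM, MCM2, MCM5, MT-CO1, MT-CO3, MT-CYB, MUC1, NFKB1, NFKB2, NFKBIA, PHGDH, PKM, PMVK, PPP2CB, RFC2, RHOA, RPL15, RPL18, RPL4, RPL7, SLC7A5, SREBF2, STK25, STRN4, TAOK2, TEAD2, TGFB1, TPX2, USP18 and VIM. Among the 10 highest it also names HIST1H1B and RNU2-2P, a U2 RNA row. RNU2-2P stood at 3.65 relative to the median gene, where it did not pass the test (adjusted p = 0.0606). Summed with RNU2-1 and with WDR74, a gene that overlaps it, RNU2-2P stood at 1.19. In the table of the authors, 57 rows carry a yes in the column for significance, 45 higher and 12 lower by the authors' mean TPM, and 4265 have an adjusted p under 0.05. Of the 56 such yes rows among the tested ones, 55 also changed relative to the median gene. Of 4116 tested rows with an authors' adjusted p under 0.05, 2350 did. In that table STRN3 has an adjusted p of 9.50e-14 and no yes.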

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

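The tests of the alternatives relative to the median gene, of the protein-coding total, of rows sharing a symbol summed and of the length and GC trend were chosen after the data were seen. Rows tested singly per transcript, and the count-based and unit alternatives, were not run, since the values are per gene in TPM. On the deposited scale 10643 rows changed, and 8149 to 10731 under the filters, the pseudocount, the trend, the block, the summed rows and leaving out each library, but 2772 after rescaling, 3070 with TPM over protein-coding rows and 553 with a 2-fold threshold. Relative to the median gene 2772 rows changed, and 1891 to 2788 under the filter, pseudocount, trend, summed-row and length and GC settings. The count was 115 with a 2-fold threshold and 1508 to 2150 without 1 library. Over protein-coding rows, not rescaled to the median gene, 3070 changed. Without siNC replicate 1, 2 or 3 the counts were 1508, 1554 and 1604. Of these, 1450, 1514 and 1535 were the same genes in the same direction. With 5 libraries fewer rows are tested and the spread is estimated from fewer samples. The same-numbered libraries did not deviate together (correlations 0.057, -0.021 and -0.080), and only number 1 matched best with itself, so the replicate number does not pair them; with the replicate number as a block 10510 rows changed on the deposited scale and 1736 relative to the median gene, 1654 of them the same genes in the same direction. The cause of that difference was not tested.

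The STRN3 difference kept its sign throughout. As deposited it was 0.24, 0.78 after rescaling (adjusted p = 0.00896), 0.78 over protein-coding rows (0.00608), and 0.14 to 0.38 without 1 library, passing only without siNC replicate 2; its adjusted p was 0.131 to 0.27 under the other settings. Relative to the median gene it was 0.65 to 0.93 with adjusted p from 0.0063 to 0.034.

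On the deposited scale 8 lists were called, 17 without a filter, 4 at 5 TPM, 5 with the replicate block, 5 without the trend, 5 to 9 without 1 library (5 without siNC replicate 1), 1 with an estimated correlation and 22 by fry. Relative to the median gene 10 were called, 9 or 10 under the other settings, 1 with an estimated correlation and 15 by fry. Over protein-coding rows, which were not rescaled to the median gene, 8 were called. The epithelial-mesenchymal list was the one lost under the block (adjusted p = 0.0564) and 5 further settings. The mitochondrially encoded list was lost over protein-coding rows. The cause of the other differences was not tested. Of 118 genes named, 19 lost their call under some setting, 17 of them without 1 library. Among these were NF2, AMOTL2, CCDC80, STAT2, ISG15, MCL1, BAMBI, SNORA73A, FAM103A2P and a U1 row under several, and STK26, BST2, IER2, THY1, ID2 and AMH without a single siNC library each. GATA4, which did not pass, changed sign without siSTRN3 replicate 1 (-0.048). Its lowest and highest values without 1 library were -0.048 and 0.13. Over protein-coding rows, where the median row stood at -0.051, GATA4 stood at -0.0063. Of the 118 named genes, 112 were tested with a siNC library left out, 109 at 5 TPM and 101 over protein-coding rows. With summed rows 114 were tested, and 111 with the length and GC trend removed. Genes not tested under a setting could not lose their call there. Depth is unknown, so how far it limits the low genes cannot be given.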

Other observations

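Fatty acid synthesis genes were gathered in a set of 12 after the cholesterol list had been seen, and the set was not tested against other genes. Of 11 measured genes 7 rose relative to the median gene, 0 fell and 4 did not pass, with a median of 0.20 against -0.41 on the deposited scale. ACLY, which makes cytosolic acetyl-CoA, rose from 63.1 ± 1.42 to 82.3 ± 2.43 TPM (1.02, adjusted p = 3.34e-05), ACSS2 rose (0.60, adjusted p = 0.0124), and the desaturase gene SCD rose (0.33, adjusted p = 4.08e-04), whereas SREBF1, the gene of their regulator SREBP-1, stood at 0.044, adjusted p = 0.685. Of 2 nuclear long noncoding RNAs, chosen after their values were seen, MALAT1 rose from 16.9 ± 1.52 to 26.9 ± 3.39 TPM (1.26, adjusted p = 8.68e-04) and NEAT1 fell (-0.34, adjusted p = 0.0352).

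In the weighing that follows, the tests of the protein-coding total, of exchanged columns, of the 2 histone sets (some of whose values had been seen) and of S phase were chosen only after the result was seen. STRN3 was higher in the libraries labelled siSTRN3. A trend on length and GC content is argued against as the whole cause, since the log2 fold change stayed at 0.77 ± 0.12 SE with it removed. Over protein-coding rows it was 0.78 ± 0.13 SE, which decides nothing on the scaling by ribosomal RNA: that share was higher in the libraries labelled siSTRN3, so leaving it out could only raise the value. Exchanged group columns, which would turn every direction given here, could give this value and cannot be told apart from a true rise: the exact permutation p of 0.1 is the smallest 3 against 3 can give, and no second marker of the groups is known from the labels. A knockdown that had ended or had been offset by 72 h stays open as a biological explanation and was not tested.

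Ribosomal, 7SK, RMRP and histone RNA rose together. A candidate explanation is a larger share of non-polyadenylated RNA in the libraries labelled siSTRN3, for example from less complete poly(A) selection. Less complete removal of ribosomal RNA alone would lower the shares of all other RNA. Those of 7SK, RMRP and RPPH1 (0.104% to 0.262%) and of small nuclear, nucleolar and Cajal body RNAs (0.107% to 0.267%) were higher. These values argue against ribosomal RNA removal as the whole cause. The 6 listed histone genes known to make polyadenylated transcripts had a median of 0.32 and the other 14 a median of 1.35. A larger share of non-polyadenylated RNA would give a difference in this direction (exact 2-sided permutation test over the genes, p = 0.00361). That test takes genes measured in the same libraries as separate units, so its p does not measure the spread between libraries. More cells in S phase cannot be told apart from such a larger share for the histones. The G1/S list median was 0.13 ± 0.044 SE over its genes, above 0 but well under the histone median of 0.98. That SE also takes genes as separate units and does not measure the spread between libraries. The ratio that S phase would give is not known here. A change in RNA synthesis after the treatment was not tested.

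Cholesterol genes rose relative to the median gene. A trend on length and GC content is argued against as the whole cause. With it removed the list median was 0.44 ± 0.051 SE, from a bootstrap over the genes (camera, adjusted p = 1.01e-11). That SE does not measure the spread between libraries. The level of the genes does not account for the rise of the list. The list median lay above all 10000 random lists matched on mean level (percentile 100), whose middle 95% ended at 0.071. Sterol synthesis that rose with the treatment may be the cause and stays a hypothesis, because the labels could not be checked with STRN3 and the labels give no cell density.

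With 3 against 3 there are 10 splits of the libraries, too few for a share under 0.05. Every other split mixes libraries of both labels, so a group difference of any cause enters its spread and keeps its count low. The gap in counts therefore follows from any difference between the groups and does not weigh its cause. The real split changed 10643 rows on the deposited scale, and the highest of the others changed 7. Relative to the median gene the counts were 2772 and 3. For gene lists they were 8 and 2 on the deposited scale and 10 and 4 relative to the median gene.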
